A study of Mus musculus with 4 samples.

How the data were processed

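Total RNA-seq libraries of 4 mouse T-helper 2 cell samples were analysed. The labels number them as separate biological replicates and give all of them the same donor identifier, so p-values measure the spread between these samples, which may be partly technical. Whether the identifier names a single animal is not given in the sources used here. The authors deposited a table of counts per gene for each library, made with featureCounts 1.4.6-p4 on the mouse build mm10 and GENCODE release M13, per the file headers. The headers record strand option 1, paired reads with both ends aligned, exons grouped by gene, a folder name that says stranded, and 16 hours, a time that the labels do not give. The assay title in the labels is total RNA-seq, while the name of the linked protocol document speaks of poly(A) RNA. The aligner is not given in the sources used here. The tables hold no summary rows, and the counts are not normalised.

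The design fixed before the data were examined assumed TPM and expected counts. The deposited tables hold whole-number counts, so TPM was computed here from the counts and the deposited gene lengths, and alternatives that need posterior mean TPM were not run. Gene symbols and types came from GENCODE release M21 on the same build, matched by gene identifier for 99.6% of 50600 genes. Genes without a symbol held 0.56% of counts. Release M13 itself was not used here. Coordinates are those of the deposited tables, 1-based. Exons of each gene were set against exons of genes on the other strand with bedtools 2.31.1. Genes that share reads with near-identical copies, ribosomal protein genes and V segments among them, are uncertain.

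Library totals ran from 1688658 to 2222583 counts, and a count of 0 was read as up to 3 counts. Lineage lists were compared within each library as the difference of the mean of log2(TPM + 1), with an exact two-sided sign-flip test over 16 sign patterns. The pseudocount of 1 understates differences of low genes. A planned comparison of single regulators is not reported here. Variation between replicates was tested with edgeR 4.0.16 (intercept only, TMM, filterByExpr, robust quasi-likelihood fit), as the upper tail of each gene's quasi-dispersion over the trended prior with 3 residual degrees of freedom, with Benjamini-Hochberg adjustment at 0.05. The filter asks for the minimum count in every library. The test was run on simulated data for 4619 genes with 4 replicates. Of changed genes that passed the filter, it recovered 26.2% of 42 changed 2-fold in a library, 85.4% of 41 changed 4-fold and 100% of 31 changed 8-fold. Changed genes that the filter removed are not in these percentages. There were 4 false calls among 4473 unchanged genes. Lists with 5 or more tested members were tested with Fisher's exact test, and the SD of the list mean was set against 10000 random lists of like abundance, a step also tested on simulated lists. DESeq2 1.42.0 and limma 3.58.1 served as alternatives, with R 4.3.3, Python 3.11.15, scipy 1.17.1 and pandas 2.3.3.

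In all 38 gene lists were fixed before the data were examined, and so was the rule for named genes. It takes 20 lineage genes and the 2 members with the highest mean TPM of each lineage list, the 2 to 4 highest members of every other list, all members of the X and Y list and of the RNAs without a poly(A) tail, the 10 protein-coding nuclear genes with the highest mean TPM, and the 20 protein-coding genes with the smallest p among those passing the variation test, with up to 4 passing members per list. CT010467.1, Gm42418, Gm26917, Gm37376 and the partner genes on the other strand were chosen after their values were seen. Alternatives covered the pseudocount, length scaling, list membership, normalisation, count filters, the prior, the tool and leaving out each replicate in turn. Alternatives that split genes by an opposite exon, leave CT010467.1 out of the totals or ask for a mean count of 10 were chosen after seeing the data.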

Results

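Gene counts were available for 4 libraries of mouse T-helper 2 cells, the CD4 T cell subset that makes interleukin 4, differentiated in culture from strain C57BL/6NJ. The 4 libraries, named here as replicates 1 to 4, form 1 group, so every comparison is either within libraries or between replicates. Their totals were 1688658, 1705096, 2222583 and 1881293 counts in replicates 1, 2, 3 and 4. Of the 50600 genes listed, 17431 had a count in at least 1 library and 10876 in all 4. A level of 1 TPM or more was reached in all 4 libraries by 6965 genes, of which 4845 were protein-coding. Spearman's rho between pairs of libraries, across 9891 genes, ranged from 0.791 for replicates 2 and 3 to 0.869 for replicates 1 and 4. In a check for a library deposited more than 1 time, no pair agreed within sampling noise, with chi-square per degree of freedom from 3.52 to 18.5, and from 2.08 to 5.51 without CT010467.1, the gene with the most counts in replicate 3. With 3 counts as the limit that a count of 0 allows, a gene at 0 in a library could lie anywhere up to a CPM of 1.35 in the deepest library and 1.78 in the shallowest. This limit and all intervals cover counting error only.

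The counts lay mostly in genes whose exons overlap an exon of a gene on the other strand. These were 8189 genes, 16.2% of those listed, and they held 91.8 ± 1.35% of the counts (SD, n = 4). Genes with no gene opposite held 7.08 ± 1.34% (SD, n = 4) and made up 73.6% of the list. Among protein-coding genes, 22.1% had an opposite exon and these held 86.9% of the protein-coding counts. Phykpl (chromosome 11, 51584757 to 51604489), which overlaps Hnrnpab by 809 bases, had 33171, 34712, 43343 and 39551 counts in replicates 1 to 4. Tlcd1 overlaps the ribosomal protein gene Rpl23a by 506 bases and had 17228, 17046, 24354 and 18713 counts, while Rpl23a itself had 381, 366, 354 and 458. Wdr38, opposite Rpl35 by 821 bases, reached 2586 ± 195 TPM, Acat3, opposite Tcp1 by 571 bases, reached 3148 ± 95.3 TPM and Mettl23, opposite Srsf2 by 460 bases, reached 3386 ± 264 TPM (SD, n = 4). The highest protein-coding entry outside the mitochondria was Gm20721 at 12305 ± 481 TPM (SD, n = 4), opposite Gnas by 1469 bases. The next were Gm17606 at 4933 ± 361 TPM and Gm26602 at 3637 ± 492 TPM (SD, n = 4), opposite Acin1 and R3hdm4. Further genes named below with an exon opposite include Stat6 (Nab2), Il4ra (Gm44876), Il5 (Gm12214), Maf (Gm15655), Bcl6 (Gm37419), Cxcr5 (Bcl9l), Trdc (Trdv5), Usp18 (Gm44148), Car9 (Gm12454), Nfkb2 (Psd), Ddit3 (Mars), Atf5 (Il4i1), Malat1 (Gm37376), Gm5148 (Rps23-ps1), Olfr77 (Gm7808), Gm9887 (Arf6), Ccdc107 (Rmrp), Cand2 (Rpl32) and CT010467.1 (Gm42418). Ribosomal protein genes with no opposite exon held at most 0.593% of the counts of a library. All levels and counts of 0 given below are those on the counted strand. TPM is scaled over all genes; scaled over protein-coding nuclear genes, levels of the 130 named genes of that kind with counts were 4.04 to 4.55 times as high.

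Among the 13 mitochondrial mRNAs, mt-Nd6 held most counts. It is the only 1 of them on the minus strand of the mitochondrial genome (13552 to 14070) and had 27391, 25582, 26908 and 29527 counts in replicates 1 to 4. Its share of the mitochondrial mRNA counts was 92.0% in replicate 1 (95% Wilson interval 91.6 to 92.3), 87.2% in replicate 2 (86.8 to 87.5), 90.2% in replicate 3 (89.8 to 90.5) and 90.1% in replicate 4 (89.7 to 90.4). The 12 plus-strand mRNAs held 12367 counts over the 4 libraries. Among them mt-Nd5 was at 614 ± 131 TPM, mt-Nd4 at 394 ± 166 TPM and mt-Nd2 at 181 ± 65.6 TPM (SD, n = 4). By contrast, mt-Co2, mt-Atp8, mt-Atp6, mt-Co3 and mt-Nd4l had no count in any library, and mt-Nd3 had 1, in replicate 3. These lie side by side between positions 7013 and 10173, and why they were at or near 0 was not tested. The 8 minus-strand transfer RNA genes held 10369 counts and the 14 plus-strand ones 147.

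**Figure D1:**
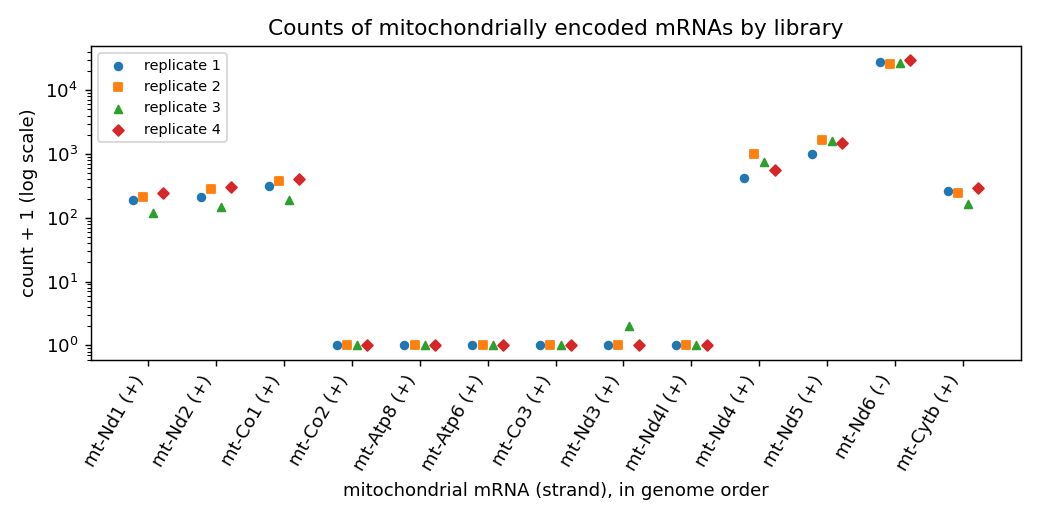
Counts plus 1 (vertical axis, log scale) of the 13 mitochondrial mRNAs in genome order (horizontal axis, strand in brackets), with 1 point per library. mt-Nd6, on the minus strand, lies between 25582 and 29527 counts, above every other mitochondrial mRNA in each library.

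All 18 T cell identity genes had counts in all 4 libraries, at low levels. The highest was Cd247, the zeta chain of the T cell receptor complex, at 167 ± 8.24 TPM (SD, n = 4), and it overlaps Pou2f1 on the other strand by 3007 bases. Without an opposite exon, the receptor constant genes Trac and Trbc2 were at 22.4 ± 8.29 and 15.6 ± 6.74 TPM and the adhesion receptor gene Cd2 at 15.1 ± 4.54 TPM (SD, n = 4). In contrast, 44 of 63 markers of other cell types had no count in any library and their median was 0 TPM in each. Of the 63, 57 had no opposite exon, and 42 of these 57 had no count. Zeros were common among all genes too, since 17431 of the 50600 listed had a count in any library. Of the CD8 and cytotoxic markers, Gzma, Gzmb and Nkg7 had no count and Cd8b1 was at 3.92 ± 2.29 TPM. The B cell genes Cd79a and Ighm were at 8.09 ± 2.2 and 6.4 ± 3.78 TPM, and the antigen presentation gene Cd74 of the dendritic cell list at 6.6 ± 2.71 TPM (SD, n = 4). Csf1r, the receptor gene of macrophages, stood out at 155 ± 14.5 TPM (SD, n = 4), and it overlaps Hmgxb3 on the other strand by 871 bases. Alas2, of the erythroid list, was at 8.72 ± 3.2 TPM (SD, n = 4) and overlaps Apex2 by 311 bases. Markers of natural killer cells, mast cells and basophils, and neutrophils had 5 of 6, 6 of 7 and 6 of 8 genes at 0 in every library. Of the gamma delta T cell genes, Trdc had 6, 6, 4 and 9 counts in replicates 1 to 4.

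On the counted strand, the mean level of the Th2 lists was above that of the Th1, Th17 and follicular helper lists in all 4 libraries. It was below that of the regulatory T cell list in all 4. The mean of log2(TPM + 1) over the 29 Th2 genes exceeded that over the 12 Th1 genes by 1.02 ± 0.06, over the 10 Th17 genes by 1.56 ± 0.13 and over the 8 follicular helper genes by 0.69 ± 0.07 (SD, n = 4). Against the 11 regulatory T cell genes the difference was -0.65 ± 0.06 (SD, n = 4). An alternative chosen after seeing the data kept only members with no opposite exon. The mean differences were then 1.13 from the Th1 list, 1.30 from the Th17 list, 0.70 from the follicular helper list and -0.69 from the regulatory T cell list. Within the Th2 list, regulators and receptors held most counts. Junb was at 44.5 ± 3.51 TPM with an opposite exon of Prdx2, and Irf4, with no opposite exon, at 25 ± 6.67 TPM (SD, n = 4). Ptgdr2, the prostaglandin receptor gene of Th2 cells, was at 57.3 ± 9.1 TPM and overlaps Ccdc86 by 1031 bases, while Ccr4, with no opposite exon, was at 10.8 ± 2.49 TPM (SD, n = 4). Stat6, which relays interleukin 4 signals, was at 8.52 ± 1.43 TPM and Il4ra at 3.08 ± 0.997 TPM (SD, n = 4). Of 9 Th2 cytokine genes, 6 had no count in any library, Il5, Il13 and Il10 among them, and Il4 had 10, 12, 18 and 7 counts in replicates 1 to 4. Maf and Il1rl1 had no count either. With all members, the exact two-sided sign-flip test gave p = 0.125 (n = 4) for each of the 4 lists, the smallest value that 4 libraries allow, so none could pass 0.05. When only members with a mean TPM of 1 or more entered, the differences from the Th1 and regulatory T cell lists were 0.12 (exact p = 0.375) and -0.040 (exact p = 0.5), with libraries on both sides of 0, and that from the follicular helper list was 1.36. Without the cytokines the differences were 1.54 from the Th1 list, -0.13 from the regulatory T cell list and 1.21 from the follicular helper list, and on log2 CPM without length scaling the latter 2 were -1.40 and 0.43.

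Gata3 (chromosome 2, 9857078 to 9890034), the regulator that defines the Th2 lineage, had 17, 20, 19 and 21 counts in replicates 1 to 4 and overlaps Gm13256 on the other strand by 155 bases. Tbx21, the Th1 regulator, has no gene opposite and had no count. On the counted strand Gata3 was thus at least 16.1-fold higher per kilobase than Tbx21, with 3 counts over the group as the limit. Against Bcl6, the follicular helper regulator with 6 counts in all, the ratio per kilobase was 21.6 (95% exact interval 9.49 to 60.7). Foxp3, the regulatory T cell regulator (chromosome X, 7579676 to 7595243), had 707, 725, 858 and 748 counts, and its exons overlap Ccdc22 on the other strand by 590 bases. On the log2(TPM + 1) scale Gata3 differed from Tbx21 by 2.27 ± 0.16, from Bcl6 by 2.05 ± 0.31 and from Foxp3 by -4.97 ± 0.12 (SD, n = 4), each with an exact two-sided p of 0.125. If the counted strand is opposite to the transcripts, neither these ratios nor these differences would measure expression. Some other lineage genes had few counts or none. Ifng had 1 count in all, Cxcr3 and Il17a had none, and Ccr8 and Cxcr5 were at 2.93 ± 1.54 and 1.91 ± 0.401 TPM (SD, n = 4). Il12rb2 of the Th1 list was at 22.2 ± 2.11 TPM and overlaps Serbp1 by 1519 bases.

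**Figure D2:**
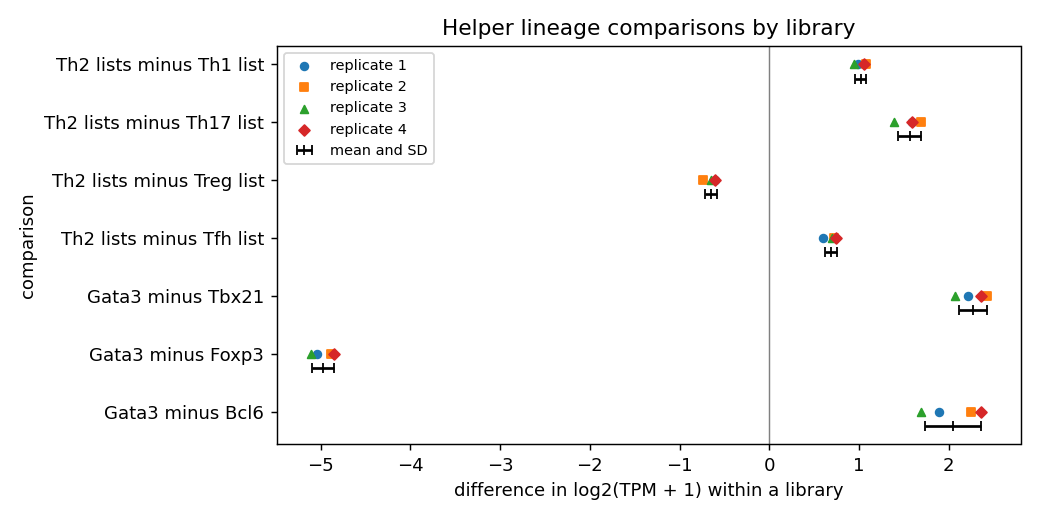
Difference in log2(TPM + 1) within each library (horizontal axis) for 7 lineage comparisons (vertical axis), with 1 point per library and the mean and SD below them. The comparisons with the regulatory T cell list and with Foxp3 lie below 0 in all 4 libraries, at means of -0.65 and -4.97, and the others lie above 0.

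All 14 DNA replication genes had counts in all 4, with the clamp gene Pcna at 23.5 ± 6.48 TPM and the helicase gene Mcm3 at 22.6 ± 8.71 TPM (SD, n = 4), both without an opposite exon. Gins2 reached 149 ± 12.7 TPM and overlaps Gse1 by 2758 bases. In the mitosis list 7 of 14 genes had counts in all 4 libraries, and Ccna2 was at 198 ± 5.4 TPM with 510 bases opposite Exosc9, against 2.74 ± 1.18 TPM for Top2a and 1.66 ± 0.757 TPM for Mki67 (SD, n = 4). All 13 glycolysis genes had counts in all 4 libraries, Ldha at 30.4 ± 9.57 and Pkm at 25.5 ± 8.53 TPM (SD, n = 4). In all 4 libraries counts were held by 6 of 8 heat shock genes, with the other 2 at 0 throughout, and by 11 of 12 unfolded protein response genes. The chaperone genes Hspa8, Hsp90aa1 and Calr of these lists were at 86.5 ± 24.7, 60.8 ± 16.6 and 86.8 ± 24.2 TPM (SD, n = 4). Of the amino acid response, Ddit3 was at 201 ± 26.5 and Atf5 at 174 ± 8.34 TPM, both with an opposite exon, and Atf4, with none, at 20.8 ± 6.36 TPM (SD, n = 4). Cholesterol synthesis had counts in all 4 libraries for 12 of 14 genes, led by Sqle at 13.5 ± 0.306 TPM, and the interferon response for 4 of 13, led by Usp18 at 10.2 ± 2.03 TPM (SD, n = 4). Of the T cell activation list, Myc was at 25 ± 10.2, Tnfrsf4 at 14.9 ± 6.9 and Il2 at 14.7 ± 7.25 TPM, and of the naive and memory list Tcf7 was at 27.5 ± 9.48 and Ccr7 at 10 ± 3.78 TPM (SD, n = 4). Among inhibitory receptors Btla was highest at 14.9 ± 4.89 TPM, and among NF-kB targets Nfkb2 at 26.4 ± 1.46 TPM (SD, n = 4). In the hypoxia list, Car9 was highest at 8.2 ± 2.14 TPM (SD, n = 4).

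Ribosomal protein genes, among the most abundant messages of growing cells, held 0.636 ± 0.149% of TPM (SD, n = 4). Rpl36, Rps24 and Rpl4, with no opposite exon, were at 519 ± 177, 393 ± 127 and 309 ± 70.9 TPM (SD, n = 4). Replication-dependent histone genes had 4, 2, 11 and 12 counts in replicates 1 to 4, over 68 genes. The 10 other RNAs without a poly(A) tail had 2, 3, 5 and 1 counts, with Rn7sk at 2 counts and Terc at 3 in all. These values may not bear on how RNA was selected, since the counted strand may be opposite to the transcripts. Of the nuclear long noncoding RNAs, Malat1 was at 6.07 ± 1.04 TPM and Neat1 at 0.128 ± 0.0701 TPM (SD, n = 4). T cell receptor beta V segments had 104 counts in all, in 19 of 35 segments, with Trbv13-2 highest at 9.97 ± 2.07 TPM. Their effective number per library was 8.93 ± 0.865 (SD, n = 4) and 13.1 with the libraries pooled. The alpha V segments had 49, 70, 50 and 57 counts in replicates 1 to 4.

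Between replicates, 22 of 4918 tested genes varied more than their abundance predicts in edgeR's quasi-likelihood test, one-sided, at an adjusted p under 0.05. CT010467.1, a ribosomal RNA gene (chromosome 17, 39846353 to 39848827) chosen after its values were seen, had 21809, 86102, 208884 and 30455 counts in replicates 1 to 4, with an adjusted edgeR p of 4.54e-15. Its share of the library ran from 1.29% in replicate 1 to 9.4% in replicate 3. Among protein-coding genes the smallest p belonged to Gm5148, with 990, 1157, 2966 and 1994 counts and an adjusted edgeR p of 5.04e-05. The RNA helicase gene Ddx1 had 22, 119, 180 and 54 counts and the odorant receptor gene Olfr77 had 127, 61, 27 and 15, both at an adjusted edgeR p of 0.00019. Hnrnpab, an RNA-binding protein gene, had 470, 319, 639 and 1008 counts at an adjusted edgeR p of 0.000835. Rap1b, a small GTPase gene, had 99, 65, 142 and 285. Gm9887, Ccdc107 and Cand2 also passed, with Ccdc107 at 11, 57, 93 and 37 counts. The count of calls was also 22 with DESeq2 size factors, but 3 with library totals only, 1 with limma on log2(TPM + 1) and 11 without replicate 4, of which 10 were among the 22.

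The mitochondrially encoded list was the 1 of 11 lists tested that was enriched among the varying genes. By the median F of each list against random lists, 6 of 11 passed: T cell identity, DNA replication, glycolysis, heat shock, ribosomal proteins and the mitochondrially encoded list. Of the mitochondrially encoded list's 7 tested members 2 passed, mt-Nd4 with 426, 1010, 743 and 556 counts and mt-Co1 with 317, 378, 189 and 406, and 6 passed when adjusted over the list alone. Fisher's exact test, one-sided, gave p = 0.000396 and an adjusted p of 0.00435. That test treats the genes of a list as independent, which they are not, so these p-values may overstate the evidence. The call was lost without replicate 2, without replicate 3 and without replicate 4, each leaving 0 lists passing and 1 list at an unadjusted p under 0.05. For heat shock 3 of 5 tested genes, and for DNA replication 1 of 9, passed when adjusted over the list alone, while 0 passed over all genes in edgeR. The SD over libraries of the list mean lay at percentile 100 of random lists of like abundance for DNA replication and ribosomal proteins, 99.99 for T cell identity, 99.49 for heat shock, 99.06 for glycolysis and 39.2 for Th2 receptors, as a description. Replicate 3 had the lowest share of counts in genes with no gene opposite, 5.51%. The mean of log2(TPM + 1) was also lowest there in all 11 lists tested, not only in the 6 that passed by the median F. For T cell identity it was 3.47, 3.54, 2.81 and 3.79 in replicates 1 to 4.

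**Figure D3:**
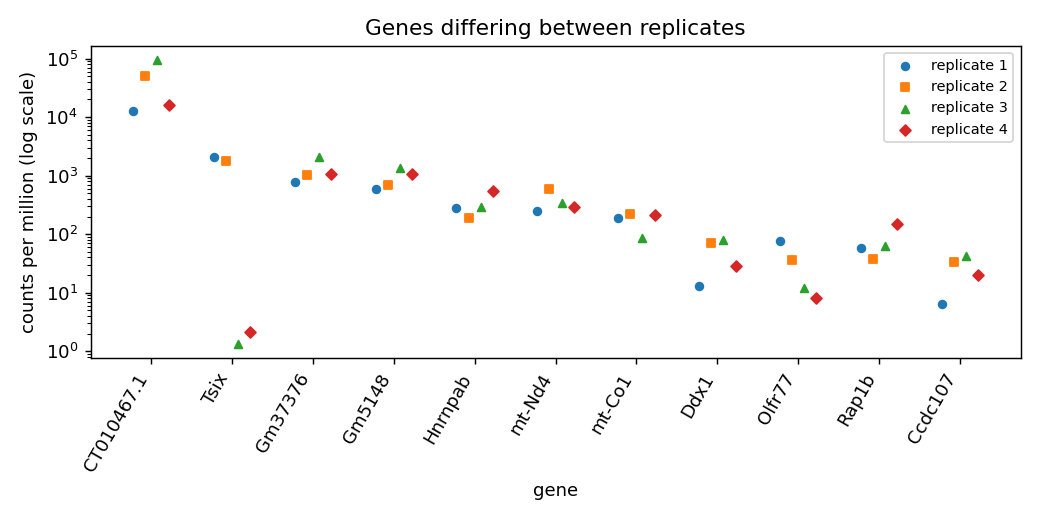
CPM (vertical axis, log scale) of 11 genes (horizontal axis) in each library, with 1 point per library. CT010467.1 spans a CPM of 12915 to 93982.5 and Tsix a CPM of 1.35 to 2052 across the 4 libraries.

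The 6 genes of the X and Y list differed in counts between the libraries. Tsix (chromosome X, 103431517 to 103484957), the antisense partner of Xist, had 3465 counts in replicate 1, 2990 in replicate 2, 3 in replicate 3 and 4 in replicate 4. Xist, which silences an X chromosome, had 71, 89, 2 and 8 counts, and overlaps Tsix by 1943 bases. Ddx3y had 0, 0, 7 and 7 counts, Eif2s3y 0, 0, 1 and 9, Kdm5d 0, 0, 0 and 8, and Uty 0, 0, 0 and 3. Sex was not collected, per the labels. The minimum counts required in every library kept Tsix and the rest of this list out of the variation test.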

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

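The tests of low sequencing depth, of library size for Tsix and of sex by Ddx3y, Eif2s3y, Kdm5d and Uty were chosen after the values were seen. The design has 1 group and names no biological explanation for these patterns; antisense transcription and sex were tested as such all the same.

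T cell identity genes held few counts while mt-Nd6 held most mitochondrial mRNA counts. Low sequencing depth leaves the shares of abundant genes as they are and is argued against by ribosomal protein genes with no opposite exon, which held at most 0.593% of counts in a library. Genuine antisense transcription was tested by protein-coding counts, of which at least 84.3% in each library lay in genes with an opposite exon. That share cannot decide it, since antisense RNA is counted only where an annotated exon lies on its strand. The same 0.593% came out as predicted for counting on the strand opposite to the transcripts, which stays open as a candidate explanation. If so, counts of genes with an exon opposite, Foxp3 and Csf1r included, may come largely from the partner, and the low values and zeros of genes without one, such as Irf4, Trac, Pcna, Il13, Tbx21 and Gzmb, would not measure their expression, so the lineage differences would not either.

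Tsix had 3465, 2990, 3 and 4 counts in replicates 1 to 4. Library size is argued against, since the smallest ratio between replicates 1 or 2 and replicates 3 or 4 was 747.5, while totals differed by 1.32-fold. Libraries from animals of different sex stay a candidate explanation. Together, Ddx3y, Eif2s3y, Kdm5d and Uty had 8 counts in replicate 3, 27 in replicate 4 and none in replicates 1 and 2. In replicate 3 these were 7 of Ddx3y and 1 of Eif2s3y. Against a difference in sex stands the donor identifier, the same for all 4 libraries in the labels. Whether this identifier names a single animal is not given in the sources used here. The test on the other Y genes could not decide on sex: 3 libraries had a count of them, 1 each. If the counts were taken on the strand opposite to the transcripts, those of Tsix may come from Xist, which it overlaps by 1943 bases. Gm27520, which overlaps Xist by 81 bases, had 493, 419, 2 and 0 counts in replicates 1 to 4.

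CT010467.1 held a different share of counts in each library. Ribosomal RNA left in the libraries to different extents cannot be told apart from other sources. Of 2 other genes linked to ribosomal RNA with 100 counts or more, both ranked the libraries as CT010467.1 did by counts, but 1 did by CPM, so the outcome rests on the scale. That gene was Gm26917, while Gm42418 was at a CPM of 78.6 in replicate 2 and 73.8 in replicate 3. Gm42418 also overlaps CT010467.1, so its ranking is weak evidence.

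Of 129 values checked, 9 had a library far from the other libraries, and chance gives about 1 in 20, or 6.45 of them, so the number itself is close to chance. Replicate 3 was low in the share of mitochondrially encoded genes, at 3.6% of TPM against 4.5 to 4.67%. It was low in Ccr7 at 4.4 TPM against 11.4 to 12.2, in Trac at 10.02 against up to 27.5, in Csf1r at 133 against 162 to 163, and in Trav13n-3 at 25.8 against 45.8 to 46.4. It was high in Tlcd1 at 3254 TPM against 2913 to 2954. Replicate 2 was low in Il21 at 3.14 TPM against 5.47 to 5.93. Replicate 4 was high in Myc at 40.2 TPM against 19.0 to 21.7 and low in Cd79a at 4.82 against 8.82 to 9.53.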

How the results depend on the processing

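Alternatives that split genes by an opposite exon, leave CT010467.1 out of the totals or ask for a mean count of 10 were chosen after seeing the data. The mean lineage differences reported kept their sign under every alternative run, but with members of mean TPM of 1 or more single libraries lay on both sides of 0 against the Th1 (0.12) and regulatory T cell (-0.040) lists, while the follicular helper difference was 1.36. No alternative could pass 0.05 with 4 libraries. Their size moved with the pseudocount: Gata3 differed from Tbx21 by 5.29 at a pseudocount of 0.1 and by 0.82 at 5, and the Th2 lists from the Th1, Th17 and regulatory T cell lists by 1.88, 3.02 and -1.35 at 0.1 and by 0.48, 0.73 and -0.35 at 5. At 5 the follicular helper difference was 0.45. On log2 CPM without length scaling the regulatory T cell difference was -1.40, the follicular helper difference 0.43, and Gata3 differed from Tbx21 by 4.34 and from Bcl6 by 3.17. Without the cytokines the Th2 lists differed from the Th1 list by 1.54 in place of 1.02, from the regulatory T cell list by -0.13 in place of -0.65, and from the follicular helper list by 1.21 in place of 0.69. With Th17 no member reached a mean TPM of 1, and that alternative gave no value. Alternatives with posterior mean TPM were not run. The number of varying genes, 22, was 3 with library totals only, 56 with no filter except genes at 0 in every library, 5 with a mean count of 50 or more, 9 with a non-robust prior, 10 with protein-coding genes only and 1 with limma. It was 11 with genes with an opposite-strand exon only, 10 with genes without one, 44 with a mean count of 10 or more and 6 with library totals without CT010467.1. Leaving out a replicate gave 11 to 21. Fewer genes were tested with the stricter filter and the gene subsets, but the cause was not tested for any alternative. Of the 10 calls among genes without an opposite-strand exon, 3 were among the 22. Of the 5 calls with a mean count of 50 or more, 3 were. The number of enriched lists, 1, was 0 at a threshold of 0.01 (1 list at an unadjusted Fisher p under 0.05), 6 by the median F against random lists (T cell identity, DNA replication, glycolysis, heat shock and ribosomal proteins besides), and 0 to 1 on leaving out a replicate; the cause was not tested. Genes detected in all libraries, 6965, numbered 3879 at TPM of 5 or more, by the stricter threshold itself. All 130 named-gene values rescaled over protein-coding nuclear genes moved by more than 1 SD, to 4.04 to 4.55 times the TPM given. Genes under about 10 counts, most lineage cytokines among them, are imprecise at this depth. Why these genes were low was not tested.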

Other observations

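The correlation, the tally and the genes named below were chosen after some of the counts were seen. Of 20 noncoding genes opposite members of the T cell lists, 8 had a mean of 100 counts or more per library and 10 a mean under 10, of which 2 had no count. Among the low ones were Gm15655, opposite Maf, with 5 counts in all, Gm12214, opposite Il5, with 10 and Gm12223, opposite Csf2, with 12. Among the high ones, Gm13256, opposite Gata3 by 155 bases, had 975 ± 139 counts per library (SD, n = 4), and Gm44876, opposite Il4ra by 571 bases, had 726.5 ± 56.7. Gm48719, opposite the T cell receptor gene Cd3e, had 2816 ± 167 counts and Gm16008, opposite Tnfrsf18, 3933 ± 383 (SD, n = 4). Opposite naive T cell genes, Bach2os had 2673 ± 527 and Gm43352, opposite Lef1, 541 ± 43.5 counts (SD, n = 4). Opposite metabolic and folding genes, Gm26762 at Gpi1 had 7160 ± 1304 and 1810014B01Rik at Hsp90b1 14367 ± 2595 counts (SD, n = 4). Gm37376, opposite Malat1, had 1323, 1777, 4637 and 1991 counts in replicates 1 to 4.

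Across 1237 noncoding genes with 1 opposite protein-coding gene and 200 or more shared bases, Spearman's rho between their counts per overlapping kilobase and the partner's own counts per kilobase was 0.652 (permutation p = 1e-05, two-sided, the smallest that 100000 permutations give). This correlation is across genes, which are not independent replicates. On counts without scaling to length, rho was also 0.652. Both sides of the correlation are counts on the counted strand, so it does not test whether the counts of a gene follow the transcripts of the gene opposite.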
